A study of Mus musculus with 10 samples.

How the data were processed

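The series measured transcripts by RNA sequencing in 10 libraries of sorted mouse regulatory T (Treg) cells. The labels name total RNA, TRIzol extraction, library construction at BGI Genomics and the BGISEQ-500 sequencer; they do not state whether the libraries kept the strand. Treg cells came from Foxp3YFP-cre mice, in which a fluorescent reporter marks cells that express Foxp3. Groups were taken from the sample titles: LN (lymph nodes of tumour-free mice, 4 libraries), Hepa1-6 (tumours of an injected mouse hepatoma line, day 23, 4 libraries) and E.G7 (tumours of an injected mouse T lymphoma line derived from EL4, day 21, 2 libraries). Nothing in the labels says that replicates came from separate animals, so p-values measure the spread between these libraries, which may be technical. Replicates were compared before averaging, over genes with a summed count of at least 20. Within each group every pair differed by more than sampling noise, with a chi-square per degree of freedom from 7.42 to 18.91, so that none was treated as a repeat deposit.

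The deposited count table holds whole-number read counts for 55291 genes, with exon coordinates and gene lengths, in the layout that featureCounts writes, per the file headers. Per the submitters' processing notes the tools were HISAT2, featureCounts, Subread, RSEM and DESeq2, with the mm10 genome build; no versions, roles or annotation release are given in the sources used here. A deposited FPKM table per library lists 12930 genes; FPKM values are the authors' counts scaled by gene length and by a library size that differs from the total count by a constant in each library. The other values below were computed from the deposited counts. Because the strand setting is not given in the sources used here, genes that overlap another gene, and members of families with near-identical copies (haemoglobin, killer-lectin, MHC and chitinase-like genes), are uncertain in level.

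Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (20068 genes), libraries were scaled by TMM, and one quasi-likelihood model with a term per group was fitted to the 10 libraries with robust settings. The biological coefficient of variation was 13%. The 3 contrasts between groups were tested, with Benjamini-Hochberg adjusted p under 0.05 as the threshold and no minimum fold. CPM values are TMM-scaled. SE is the log2 fold change divided by the square root of the quasi-likelihood F. Where a group had no count for a gene, the fold is a lower bound against 3 counts over the whole group, a floor of 0.0295 CPM in LN, 0.0309 CPM in Hepa1-6 and 0.0555 CPM in E.G7 on the TMM scale. Where a group had 1 to 3 counts, the ratio is given with an exact 95% interval. Floors and intervals cover counting error only.

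A total of 27 gene lists, written before the data were examined, were tested with camera in limma 3.58.1 on log2 CPM (prior count 2), with an inter-gene correlation of 0.01 and adjustment over the 27 lists of a comparison. Camera with an estimated correlation and fry were run beside it. The lists cover T helper subsets, Treg identity and function, homing, signalling, metabolism, the cell cycle, handling stress, and markers of other cell types: B cells, macrophages and neutrophils, dendritic cells with MHC class II, CD8 T and NK cells, hepatoma, immature thymocytes, stroma and endothelium, and erythroid cells. The genes named per comparison follow a rule fixed at the same time. It takes 15 fixed genes and the 5 largest log2 fold changes in each direction among genes past the threshold. Such genes needed a mean of at least 10 CPM in the higher group and no overlap between the libraries of the groups; predicted genes, pseudogenes and antigen receptor segments were excluded. It also takes 2 to 4 members of each list with the smallest adjusted p (2 were used). Results of some genes that the rule takes are not reported here.

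Model and lists were tested on simulated data with 200 changed genes. For Hepa1-6 against LN, among 19143 genes, 41.5% of 1.5-fold, 60.3% of 2-fold and 87.5% of 4-fold changes were recovered, and 5.5% of calls were false. The shares for E.G7 against LN, among 19098 genes, were 30.3%, 63.1% and 82.3%, with 6.7% false calls. For Hepa1-6 against E.G7, among 19125 genes, they were 24.6%, 54.0% and 78.0%, with 5.0% false calls. A list raised 2-fold was called and 0 of the other lists simulated for that comparison were. Simulated genes varied independently and few were changed, while in the data 68% were called for Hepa1-6 against LN. The simulations therefore do not test the preset correlation or the share of false calls in the data.

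Alternatives fixed before the data were examined were RLE and upper-quartile scaling, no filter, a filter of 10 CPM, DESeq2 1.42.0, limma-voom, fits of only the groups compared, a replicate block, a test against a fold of 1.5, and limma on log2(FPKM + 1) and log2(FPKM + 0.1) of genes above 1 FPKM in at least 2 libraries or without that filter. Each library was also left out in turn. After the data were seen, 2 more were added: scaling to 10 pan T cell genes, and leaving out 1787 genes whose LN mean was under 1 CPM while the mean over the libraries was at least 1 CPM. For the correlation of fold changes, the spread used to judge movement was the SD over the fits that leave out a library (0.0202). Figures were drawn with matplotlib 3.10.9.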

Results

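Transcripts were counted in Treg cells sorted from lymph nodes of tumour-free mice (LN, n = 4), from subcutaneous Hepa1-6 hepatoma (n = 4) and from subcutaneous E.G7 lymphoma (n = 2). Total counts per library were 22665563 to 24472849 in LN, 26224286 to 26665325 in Hepa1-6, and 26585350 and 26663336 in E.G7. Of 20068 genes tested, the first principal component of log2 CPM took 72% of the variance and the next 17.3%. Mitochondrial transcripts made up 1.90% ± 0.18 (SD, n = 4) of counts in LN, 1.35% ± 0.11 (SD, n = 4) in Hepa1-6 and 1.83% ± 0.19 (SD, n = 2) in E.G7. The study asked whether Treg cells in tumours resemble a T helper subset. Per the series design, tumours hold many peripherally induced Treg cells and lymph nodes mostly thymic ones.

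In Hepa1-6 libraries, genes of the Th1 programme were higher than in LN libraries. Tbx21, which encodes the Th1 transcription factor T-bet (chromosome 11, 97098071 to 97115331, mm10), rose 18.4-fold, from 7.37 ± 1.25 to 136 ± 3.59 CPM (SD, n = 4 each, log2 4.20, SE 0.099, edgeR adjusted p = 3.41e-15). The chemokine receptor gene Cxcr3 rose 3.12-fold and Ifng, the gene for interferon gamma, 12.6-fold, while the chemokine gene Ccl5 rose 103-fold and the receptor gene Cxcr6 14.5-fold. Of the 14 Th1 list genes, 11 rose and 2 fell, with the same counts adjusted over the list alone, and the median log2 fold change was 1.81 (camera adjusted p = 0.000275, or adjusted p = 0.0229 with an estimated correlation). In the same libraries 9 of 10 CD8 T and NK cell markers rose, with Cd8a at 130 ± 3.45 against 2.27 ± 0.841 CPM (SD, n = 4 each).

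The Th2 and Th17 lists did not pass the camera test in Hepa1-6 libraries (adjusted p = 0.469 and 0.459). Gata3, the Th2 factor, stood at 423 ± 14.0 against 396 ± 17.8 CPM (SD, n = 4 each, edgeR adjusted p = 0.0914). Gata3 passed the threshold with RLE scaling (adjusted p = 0.0398), with DESeq2 (0.0453), without LN replicate 4 (0.036) and with scaling to pan T cell genes (5.44e-06). Members of both lists moved in either direction: Rora rose 4.06-fold and Ccr6 fell by 2.82 on the log2 scale, and Il1rl1 rose 2.94-fold and Ccr3 9.16-fold. Of 9 follicular helper genes, 1 rose and 7 fell (8 fell when adjusted over the list alone), with a median log2 fold change of -1.37 (camera adjusted p = 0.00267, but adjusted p = 0.0607 with an estimated correlation). Among them Cxcr5 fell by 2.76 and Slamf6 by 1.88 on the log2 scale, and Bcl6, the follicular helper factor, fell by 0.88. The macrophage and neutrophil markers (median 7.92) and CD8 T and NK markers (6.23, or 4.51 with bounds) were higher in the same libraries.

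Treg identity genes went both ways in Hepa1-6 libraries. Foxp3, which defines Treg cells (chromosome X, 7573644 to 7595245, mm10, its exons overlapping those of Ccdc22, Flicr, Gm36995 and Ppp1r3f), stood at 82.0 ± 11 against 109 ± 10.8 CPM (SD, n = 4 each, log2 -0.40, SE 0.094, edgeR adjusted p = 0.00137), a call lost with scaling to pan T cell genes (log2 -0.12, adjusted p = 0.309). Il2ra, the gene for CD25, did not pass the test (log2 0.06, adjusted p = 0.314), though it did with upper-quartile scaling (log2 -0.13, adjusted p = 0.0283) and, in the other direction, with scaling to pan T cell genes (log2 0.35, adjusted p = 3.55e-05). Ctla4 rose 3.44-fold and Gpr83 fell by 3.19 on the log2 scale. Of 14 Treg core genes, 5 rose and 6 fell, and the list did not pass the test (adjusted p = 0.788), its median log2 fold change of 0.03 and its mean of -0.06 differing in sign. Of the 3 thymic Treg genes, Nrp1 fell by 1.17 and Ikzf2 by 0.24, while Swap70 rose by 0.30 on the log2 scale, a call lost with upper-quartile scaling (adjusted p = 0.0802). The list did not pass (adjusted p = 0.354). With scaling to pan T cell genes Ikzf2 had a log2 fold change of 0.05 (adjusted p = 0.522). Those hepatoma markers that could be tested (median 10.96, or 9.42 with bounds) and macrophage and neutrophil markers (7.92) were higher in these libraries.

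Genes of effector Treg cells and of suppression rose in Hepa1-6 libraries. Entpd1, the gene for the ectonucleotidase CD39 (chromosome 19, 40612366 to 40741602, mm10), rose 3.54-fold, from 51.4 ± 3.25 to 182 ± 5.22 CPM (SD, n = 4 each, log2 1.83, SE 0.065, edgeR adjusted p = 5.45e-13). Nt5e, the gene for CD73, the enzyme that acts after CD39 to yield adenosine, fell by 0.87 on the log2 scale, from 382 ± 18.9 to 209 ± 8.51 CPM. Il10 rose 24.3-fold, Gzmb 59.5-fold, Ccr8 7.08-fold and Fgl2 19.2-fold. All 18 effector Treg genes rose (median log2 1.93, camera adjusted p = 3.93e-08, or adjusted p = 0.022 with an estimated correlation), and of 10 suppressive mediators 8 rose and 1 fell (median 2.37, adjusted p = 0.00202, but adjusted p = 0.0507 with an estimated correlation). Of 10 checkpoint receptors 7 rose and 3 fell, with Lag3 up 16.1-fold and Tigit 7.04-fold, and the list did not pass (adjusted p = 0.152), although it did with DESeq2 (0.0455). In the same libraries markers of macrophages and neutrophils (median log2 7.92), of dendritic cells and MHC class II (7.86) and of CD8 T and NK cells (6.23, or 4.51 with bounds) were higher. Il10 and Fgl2 are also known from macrophages and Gzmb from CD8 T and NK cells. How far RNA of other cells raised Entpd1 or the other genes of these lists was not tested.

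**Figure D1:**
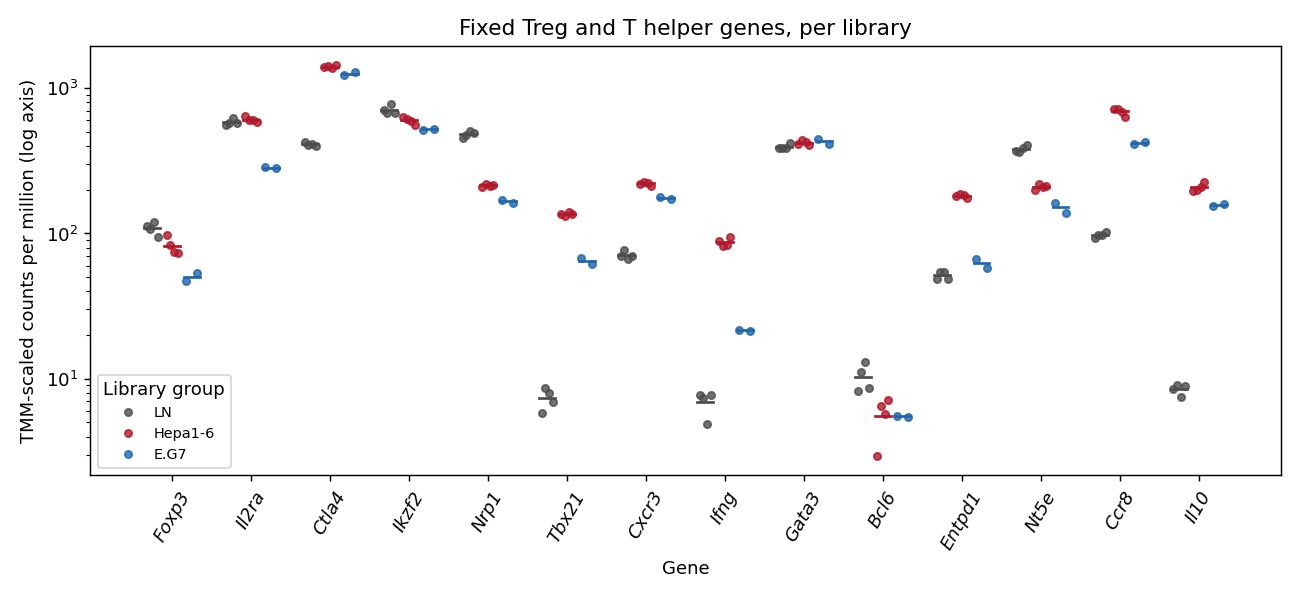
TMM-scaled CPM (log axis) of those of the 15 fixed genes that are reported here, in each library, with points for libraries and bars for group means (LN n = 4, Hepa1-6 n = 4, E.G7 n = 2). Tbx21 has means of 7.37 CPM in LN, 136 CPM in Hepa1-6 and 64.8 CPM in E.G7, and Entpd1 51.4, 182 and 62.5 CPM.

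Genes of lymphoid homing and rest fell in Hepa1-6 libraries while receptors for tissue chemokines, cell cycle genes and glycolytic genes rose. All 13 homing and rest genes fell (median log2 -2.19, camera adjusted p = 3.93e-08, or adjusted p = 0.0119 with an estimated correlation), among them the survival gene Bcl2, by 3.42, and S1pr1, a receptor for lymph node exit, by 2.19. Of 11 tissue chemokine receptors 9 rose and 2 fell (median 3.20, adjusted p = 0.000739, or adjusted p = 0.0328 with an estimated correlation). Ccr2 rose 18.6-fold and Ccr1, also a myeloid gene, 170-fold. All 22 cell cycle genes rose (median 1.85, adjusted p = 7.51e-08, or adjusted p = 0.0341 with an estimated correlation). Ccnb1 rose 6.00-fold and Rrm2 3.62-fold. All 14 glycolytic genes rose (median 2.19, adjusted p = 3.93e-08, or adjusted p = 0.025 with an estimated correlation). Tpi1 rose 15.6-fold and the glucose transporter gene Slc2a1 9.04-fold. Of 10 hypoxia genes 8 rose and 2 fell (median 3.38, adjusted p = 0.00311, or adjusted p = 0.0374 with an estimated correlation). Bnip3 rose 26.2-fold and Egln3 18.3-fold. Beside these groups, the tested hepatoma markers (median 10.96, or 9.42 with bounds) and macrophage and neutrophil markers (7.92) stood higher than in LN.

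Further lists passed the camera test in Hepa1-6 libraries only with the preset correlation. Of 12 NF-kB targets 10 rose and 2 fell (median log2 1.23, adjusted p = 0.00311, but adjusted p = 0.067 with an estimated correlation). Tnfaip3 rose 8.14-fold and Nfkbia 3.96-fold. Of 11 T cell receptor response genes 8 rose and 3 fell (median 0.57, adjusted p = 0.0201, but adjusted p = 0.116 with an estimated correlation, and lost on the FPKM scales), with Nr4a1 up 6.43-fold and Nr4a2 16.4-fold. Of 16 cholesterol synthesis genes 10 rose and 3 fell (median 0.54, adjusted p = 0.0441, but adjusted p = 0.12 with an estimated correlation). Insig1 rose 1.90-fold. That call ended without LN replicate 1 (0.0594), 3 (0.0578) or 4 (0.0511), with the replicate block (0.0536), with upper-quartile scaling (0.0662), with the filter of 10 CPM (0.143) and on the FPKM scales. Of 14 handling-stress genes, induced by tissue dissociation, 12 rose and 1 fell (median 1.29, adjusted p = 0.000523, but adjusted p = 0.0547 with an estimated correlation), with Atf3 at 417 ± 9.99 against 0.215 ± 0.182 CPM (log2 10.88, or 11.57 without LN replicate 2) and Junb up 3.28-fold. The interferon response list had 13 genes up and 5 down of 22 and did not pass (adjusted p = 0.0831, or 0.0198 with DESeq2, 0.0376 with limma-voom, 0.0412 without a filter, 0.0277 with pan T cell scaling and 0.0175 without genes under 1 CPM in LN), with Irf1 up 2.17-fold and Rsad2 7.92-fold. Macrophage and neutrophil markers, higher by a median of 7.92, moved with these lists.

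Transcripts typical of other cell types stood in the Hepa1-6 libraries. All 9 tested hepatoma markers rose. Their median log2 fold change was 10.96, or 9.42 with genes absent from LN at their bound (camera adjusted p = 3.2e-06, or adjusted p = 0.025 with an estimated correlation). The other genes of this list of 15 were too low to be tested. These were Apoa1, Ttr, Serpina1a, Serpina1b, Apob and Ahsg, at 0 to 0.433 CPM in Hepa1-6. A gene absent from LN passes the filter only if a tumour group holds it, so the filter partly fixes the count of rises and the median. Alb, the albumin gene, stood at 370 ± 9.96 CPM against 0.0389 ± 0.0315 CPM, and the keratin gene Krt8 at 463 ± 21.8 CPM, 23600 times its LN level (95% counting interval 6520 to 195000). All 14 macrophage and neutrophil markers rose (median 7.92, adjusted p = 7.77e-08, or adjusted p = 0.0257 with an estimated correlation). C1qa rose 267-fold and Mrc1 1090-fold (log2 10.08, or 10.98 without LN replicate 2). All 10 dendritic cell and MHC class II markers rose (median 7.86, adjusted p = 3.39e-06, or adjusted p = 0.0182 with an estimated correlation), with Cd74 at 4910 ± 244 CPM and H2-Aa up 286-fold. The CD8 T and NK markers had a median of 6.23, or 4.51 with bounds (adjusted p = 0.000809, or adjusted p = 0.025 with an estimated correlation). Klrd1 rose 175-fold and Klrc1 163-fold. Of the same list, Klrb1c stood at 0.597 CPM against 0.981 CPM in LN, and Ncr1 at 0.483 CPM. Of 12 stromal and endothelial markers 11 rose and 1 fell (median 6.93, or 5.29 with bounds, adjusted p = 0.000264, or adjusted p = 0.0229 with an estimated correlation). Fn1 rose 2450-fold and Sparc 873-fold. Without the genes under 1 CPM in LN the stromal list did not pass (adjusted p = 0.105). Of 5 erythroid genes 4 rose (median 7.17, adjusted p = 0.0166, but adjusted p = 0.0607 with an estimated correlation and 0.0519 on log2(FPKM + 0.1)), with Hba-a1 at 14.8 ± 0.403 CPM and Hbb-bs at 13.6 ± 2.47 CPM. The B cell list (4 up, 3 down of 10; Ighm down by 1.20, Ms4a1 up 14.1-fold) and the thymocyte list (3 up, 1 down of 5; Cd8b1 up 4.12-fold) did not pass (adjusted p = 0.95 and 0.202).

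**Figure D2:**
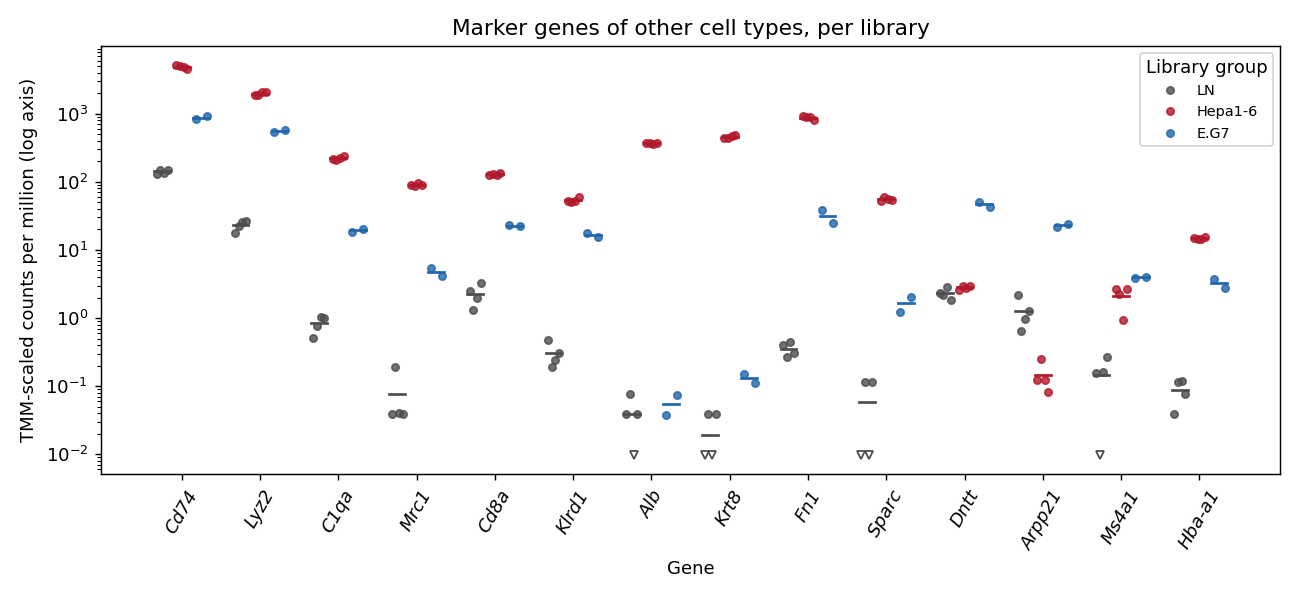
TMM-scaled CPM (log axis) of marker genes of other cell types in each library; points are libraries, bars group means, and open triangles mark libraries with no count. Alb stands at 370 CPM in Hepa1-6 and 0.0554 CPM in E.G7 libraries, and Dntt at 2.84 and 46.6 CPM.

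Ranked by fitted fold change, the rule for named genes took Mmp12, Chil3, Tnfrsf11b, Krt19 and Tspan12 as higher in Hepa1-6 libraries. No LN library had a count for them. They were at least 10100-fold, 5360-fold, 5200-fold, 4100-fold and 3500-fold higher, with Mmp12, a macrophage elastase gene, at 297 ± 17.8 CPM (SD, n = 4). The genes lower by the same rule were Gucy1a1 (26.2-fold lower, log2 -4.71, or -5.60 without Hepa1-6 replicate 2), Slc16a5 (23.5-fold), Rec8 (22.3-fold), Sorcs2 (22.1-fold) and Slc28a2b (20.2-fold, from 102 ± 6.53 to 5.03 ± 0.501 CPM). In all, 7419 genes were higher and 6237 lower than in LN, 68% of those tested, and 4721 and 2869 of them changed by at least 2-fold. Of the higher genes, 2951 had an LN mean under 1 CPM. Libraries of the groups did not overlap for 6725 higher and 5408 lower genes, where chance gives 2.86% of genes. With scaling to pan T cell genes, chosen after the data were seen, 9518 were higher and 4040 lower, and the share of calls that were higher went from 54.3% to 70.2%. With upper-quartile scaling the majority turned, with 6356 higher and 7754 lower, a share of 45%.

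In E.G7 libraries the Th1 genes were also higher than in LN, with smaller folds than for Hepa1-6 and only 2 libraries. Tbx21 rose 8.79-fold, to 64.8 ± 3.89 CPM (SD, n = 2, log2 3.14, SE 0.11, edgeR adjusted p = 1e-12). Cxcr3 rose 2.48-fold, Ifng 3.10-fold, Ccl5 32.5-fold and Cxcr6 7.23-fold. Of the 14 Th1 genes 10 rose and 3 fell, with the same counts adjusted over the list alone, and the median log2 fold change was 1.17 (camera adjusted p = 0.00676, or adjusted p = 0.0409 with an estimated correlation). Beside this, 8 of 10 CD8 T and NK markers rose (median 4.16, or 2.75 with bounds, adjusted p = 0.00253, or adjusted p = 0.0353 with an estimated correlation), with Klrd1 and Klrc1 each up 53.9-fold. That call ended without the genes under 1 CPM in LN (adjusted p = 0.0868).

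The other helper lists gave no rise in E.G7 libraries that passed the test. The Th2 list (1 up, 5 down of 10, with 6 down adjusted over the list alone; adjusted p = 0.12) included Il4ra, down by 0.57, and Stat6, down by 0.72 on the log2 scale. In the Th17 list (7 up, 2 down of 10; adjusted p = 0.227), Rora rose 5.22-fold and Ccr6 fell by 1.51. Gata3 stood at 430 ± 20.3 CPM (SD, n = 2, edgeR adjusted p = 0.0887), with adjusted p = 0.0283 under RLE scaling, 0.0281 with DESeq2, 0.0396 without LN replicate 4 and 3.49e-05 with scaling to pan T cell genes. Bcl6 fell by 0.89 (adjusted p = 0.0146), a call lost without E.G7 replicate 1 (0.0832) or 2 (0.0884) and with scaling to pan T cell genes (0.0871). Of 9 follicular helper genes 1 rose and 7 fell (median -0.99, camera adjusted p = 0.00676, but adjusted p = 0.0914 with an estimated correlation), with Cd200 down by 1.85 and Slamf6 by 1.27. Macrophage and neutrophil markers were higher by a median of 4.81 (4.73 with bounds) in the same libraries.

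Of 14 Treg core genes, 9 fell and 3 rose in E.G7 against LN libraries, a camera call (adjusted p = 0.0218) that was lost at adjusted p = 0.112 with an estimated correlation. Foxp3 fell by 1.11 on the log2 scale, to 50.2 ± 4.34 CPM (SD, n = 2; SE 0.12, edgeR adjusted p = 1.25e-06), Il2ra by 1.04, Nrp1 by 1.54, Ikzf2 by 0.44 and Gpr83 by 2.78, while Ctla4 rose 3.07-fold. The Ikzf2 call was lost with scaling to pan T cell genes (log2 -0.16, adjusted p = 0.0949). The core list had a median of -0.50, with 10 genes down when adjusted over the list alone, and its call was also lost when only the libraries of these groups were fitted (0.0507). The 3 thymic Treg genes did not pass as a list (adjusted p = 0.246). Beside Nrp1 and Ikzf2, the third, Swap70, named after its values were seen, rose by 0.42 on the log2 scale (84.1 ± 3.70 to 112 ± 10 CPM, edgeR adjusted p = 0.000131). In the same E.G7 libraries, macrophage and neutrophil markers (median 4.81, or 4.73 with bounds) and the 5 tested thymocyte genes (3.33, adjusted p = 0.00975, but adjusted p = 0.0566 with an estimated correlation) were higher. Cd8a and Cd8b1 are among these 5. Dntt stood at 46.6 ± 4.50 against 2.30 ± 0.393 CPM and Trap1a, a mouse tumour antigen gene, at 127 ± 7.92 against 0.0488 ± 0.0488 CPM (SD, n = 2 and 4).

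Effector Treg genes rose in E.G7 libraries. Entpd1 stood at 62.5 ± 6.57 CPM (SD, n = 2, log2 0.28, SE 0.077, edgeR adjusted p = 0.00538), a call lost without E.G7 replicate 1 (log2 0.18, adjusted p = 0.128) and with upper-quartile scaling (0.0793). Il10 rose 18.4-fold, Gzmb 30.8-fold and Ccr8 4.26-fold, and Nt5e fell by 1.34 on the log2 scale. Of 18 effector Treg genes 16 rose and 0 fell (adjusted over the list alone, 17 and 1; median 1.43, camera adjusted p = 1.45e-06, or adjusted p = 0.0309 with an estimated correlation). Of 10 suppressive mediators 8 rose and 2 fell (median 1.5, adjusted p = 0.00861, but adjusted p = 0.0899 with an estimated correlation). Checkpoint receptors (6 up, 4 down of 10) did not pass (adjusted p = 0.254), with Tigit up 5.38-fold and Lag3 5-fold. Markers of macrophages and neutrophils (median 4.81, or 4.73 with bounds), of dendritic cells and MHC class II (5.65) and of CD8 T and NK cells (4.16, or 2.75 with bounds) were higher in these libraries too.

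Cell cycle genes rose further in E.G7 libraries: all 22 were higher than in LN (median log2 2.81, camera adjusted p = 1.4e-12, or adjusted p = 0.0309 with an estimated correlation). Rrm2 rose 12.4-fold and Stmn1 7.23-fold. In the same libraries the thymocyte genes Dntt and Arpp21 stood at 46.6 ± 4.50 and 22.9 ± 1.28 CPM (SD, n = 2), against 2.30 ± 0.393 and 1.28 ± 0.674 CPM in LN (SD, n = 4). Trap1a stood at 127 ± 7.92 against 0.0488 ± 0.0488 CPM. All 14 glycolytic genes rose (median 1.53, adjusted p = 7.01e-09, or adjusted p = 0.0309 with an estimated correlation). Tpi1 rose 9.30-fold and Pgam1 5.66-fold. Of 16 cholesterol synthesis genes 12 rose and 1 fell (median 0.75, adjusted p = 0.00168, or adjusted p = 0.04 with an estimated correlation). Cyp51 rose 3.99-fold and Insig1 3.09-fold. Of 11 tissue chemokine receptors 9 rose and 2 fell (median 2.09, adjusted p = 0.00106, or adjusted p = 0.0353 with an estimated correlation). Ccr2 rose 6.71-fold. Of 13 homing and rest genes 11 fell and 1 rose (median -1.53, adjusted p = 2.47e-06, or adjusted p = 0.0217 with an estimated correlation), with Bcl2 down by 2.95 and Id3 by 2.74. Of 22 interferon response genes 6 rose and 15 fell (median -0.52, adjusted p = 0.00546, but adjusted p = 0.0923 with an estimated correlation), with Usp18 down by 2.03 and Irf9 by 1.26. Of 12 NF-kB targets 7 rose and 2 fell (median 0.61, adjusted p = 0.0313, but adjusted p = 0.15 with an estimated correlation). Tnfaip3 rose 6.37-fold and Nfkbia 3.19-fold. The NF-kB call was lost with upper-quartile scaling (adjusted p = 0.0542), with the filter of 10 CPM (adjusted p = 0.109) and on the FPKM scales. The lists for the T cell receptor response (adjusted p = 0.0577; Nr4a1 up 5.50-fold, Nr4a2 11.2-fold), hypoxia (adjusted p = 0.0574; Egln3 up 16.6-fold, Bnip3 5.73-fold) and handling stress (adjusted p = 0.111; Atf3 up 276-fold, with log2 8.11, or 8.79 without LN replicate 2, and Junb 2.42-fold) did not pass. The receptor response passed without E.G7 replicate 1 (adjusted p = 0.0419) or 2 (0.0364), hypoxia without LN replicate 1 (0.048) or 4 (0.0435) or E.G7 replicate 2 (0.0442), and handling stress with DESeq2 (0.0219) and limma-voom (0.0371). The receptor response and hypoxia also passed with DESeq2 (adjusted p = 0.0138 and 0.0355), without a filter (0.018 and 0.014) and with scaling to pan T cell genes (0.0491 for each), and the receptor response with limma-voom (0.0297) and without genes under 1 CPM in LN (0.0317).

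Markers of other cells were present in E.G7 libraries too. All 14 macrophage and neutrophil markers rose (median log2 4.81, or 4.73 with bounds, camera adjusted p = 8.37e-07, or adjusted p = 0.0353 with an estimated correlation), with Lyz2 at 552 ± 26.7 CPM (SD, n = 2) and C1qa up 23.1-fold. All 10 dendritic cell and MHC class II markers rose (median 5.65, adjusted p = 8.43e-06, or adjusted p = 0.0217 with an estimated correlation). H2-Aa rose 52.1-fold and H2-Eb1 51.4-fold. Of 5 tested thymocyte genes, which immature T cells express, 4 rose (median 3.33, adjusted p = 0.00975, but adjusted p = 0.0566 with an estimated correlation). Dntt stood at 46.6 ± 4.50 CPM and Cd8a rose 10-fold. Cd8a and Cd8b1 are also on the CD8 T and NK list. Of the 8 thymocyte list genes, Rag1, Rag2 and Ptcra were too low to be tested. In E.G7 libraries Rag1 and Rag2 had no count and Ptcra stood at 0.0554 CPM. Of 12 stromal and endothelial markers 11 rose and 1 fell (median 4.50, or 3.42 with bounds, adjusted p = 0.00111, or adjusted p = 0.0309 with an estimated correlation). Fn1 rose 88.6-fold and Pdgfrb stood at 1360 times its LN level (95% counting interval 244 to 53900). Its count of 1 in LN came from replicate 2, without which the fitted log2 fold change went from 9.82 to 11.40. That list did not pass without the genes under 1 CPM in LN (adjusted p = 0.233) or on log2(FPKM + 1) (adjusted p = 0.14, or 0.0807 without its filter). Of 5 erythroid genes 4 rose and 1 fell (median 4.85, adjusted p = 0.0492, but adjusted p = 0.111 with an estimated correlation). Hba-a1 rose 34.6-fold and Hbb-bs 81.2-fold. That call was lost without LN replicate 2 (0.0628) or 4 (0.0535) or any Hepa1-6 replicate, and with RLE scaling (0.0566), DESeq2 (0.0886), limma-voom (0.112), the FPKM scales, pan T cell scaling (0.0965) or only the groups compared (0.128). The hepatoma list (5 up, 1 down of 9; Trf up 62.9-fold, Gpc3 at least 58.4-fold) and the B cell list (5 up, 2 down of 10; Ms4a1 up 26.3-fold, Cd79a 2.77-fold) did not pass (adjusted p = 0.12 and 0.273).

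Ranked by fitted fold change, the same rule took Pcdh10, Dclk3, Apod, Sema6a and Wif1 as higher in E.G7 libraries. For genes without counts in a group the fitted value, and so the rank, depends on the prior count. Pcdh10, Dclk3 and Sema6a had no count in LN and were at least 873-fold, 723-fold and 560-fold higher. Apod was at 5370 times its LN level (95% counting interval 964 to 212000) and Wif1 at 4030 times (1110 to 33300). The count of 1 for Apod in LN came from replicate 3, without which its fitted log2 fold change went from 11.80 to 13.38. Lower were Xist, the RNA that silences an X chromosome in female cells (20.6-fold, from 158 ± 9.21 CPM in LN, n = 4, to 7.66 ± 0.889 CPM, n = 2), Gpr15 (9.69-fold), Kcnip2 (9.23-fold), Gucy1a1 (8.84-fold) and Gbp2b (8.53-fold). In all, 6554 genes were higher and 5459 lower, 59.9% of those tested, with 3829 and 2848 changed by at least 2-fold; 2138 of the higher genes had an LN mean under 1 CPM. Groups did not overlap for 6439 higher and 5370 lower genes, where chance gives 13.33%. With scaling to pan T cell genes 8368 were higher and 3693 lower, a share of higher calls of 69.4% against 54.6%. Upper-quartile scaling turned the majority here too, with 5857 higher and 6266 lower (48.3%).

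**Figure D3:**
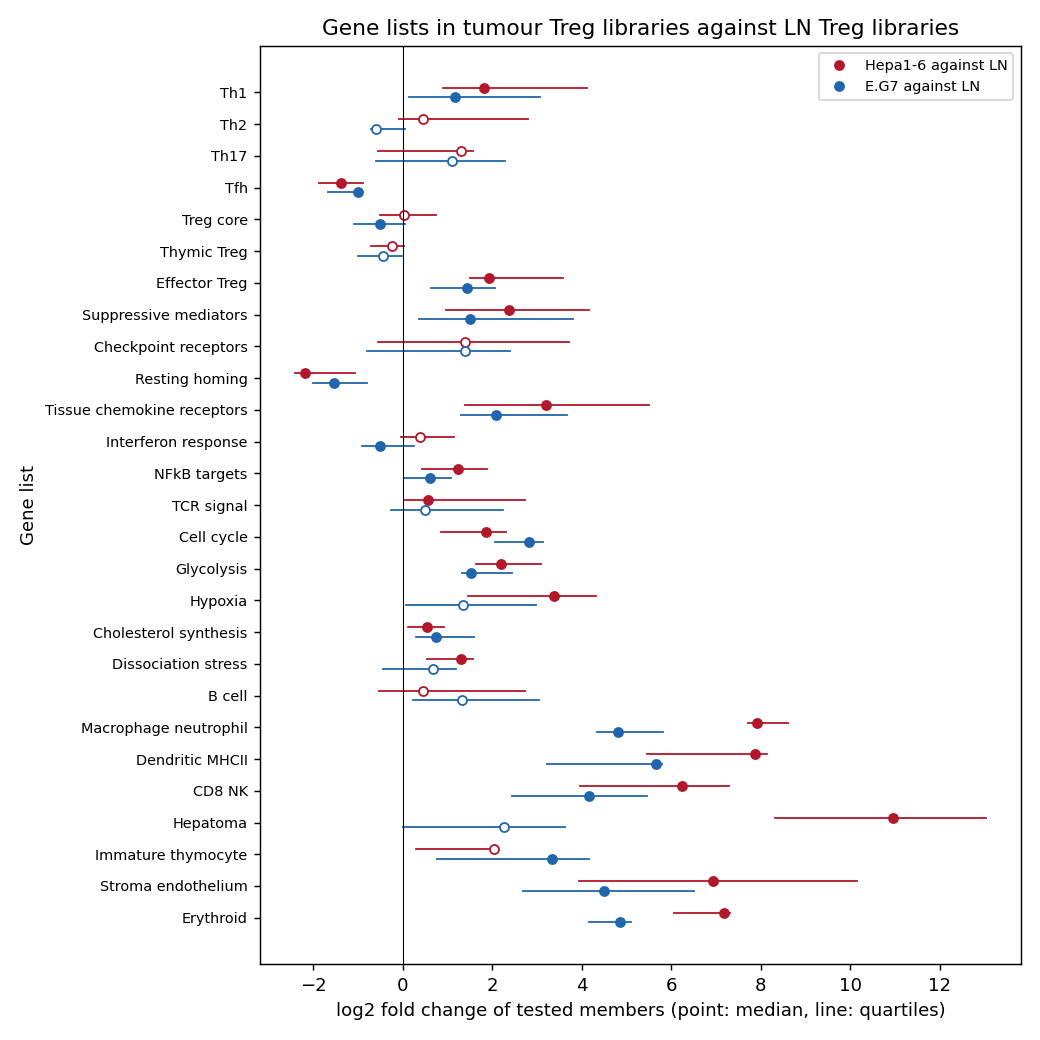
Median log2 fold change against LN of the tested members of each of 27 gene lists (points; lines span the quartiles) for Hepa1-6 and E.G7; filled points passed the camera test with the preset correlation. The Th1 list has medians of 1.81 and 1.17, and the homing and rest list -2.19 and -1.53.

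Both tumours were compared with the same LN libraries, so their fold changes share chance deviations. Genes higher in both numbered 4847 and lower in both 4208, and 654 were called in opposite directions. These became 4045 higher and 5149 lower with upper-quartile scaling, and 6778 and 2630 with scaling to pan T cell genes. Independent lists would share 2423 and 1697. In 20 simulations of unchanged groups 0 genes were called in both. With no changed gene almost none can be called there, so that count does not measure what shared LN libraries add among called genes. With the LN libraries split between the comparisons, 4184 to 4332 were higher and 3543 to 3628 lower in both. Pearson's r across genes, which are not independent replicates, was 0.66, against 0.41 simulated and 0.62 to 0.63 with split controls. The covariance was 3.48 against 0.0417 simulated. Among the fixed genes, Tbx21, Cxcr3, Ifng, Ctla4, Ccr8, Il10 and Entpd1 were called higher in both, and Foxp3, Nrp1, Ikzf2, Bcl6 and Nt5e lower in both.

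**Figure D4:**
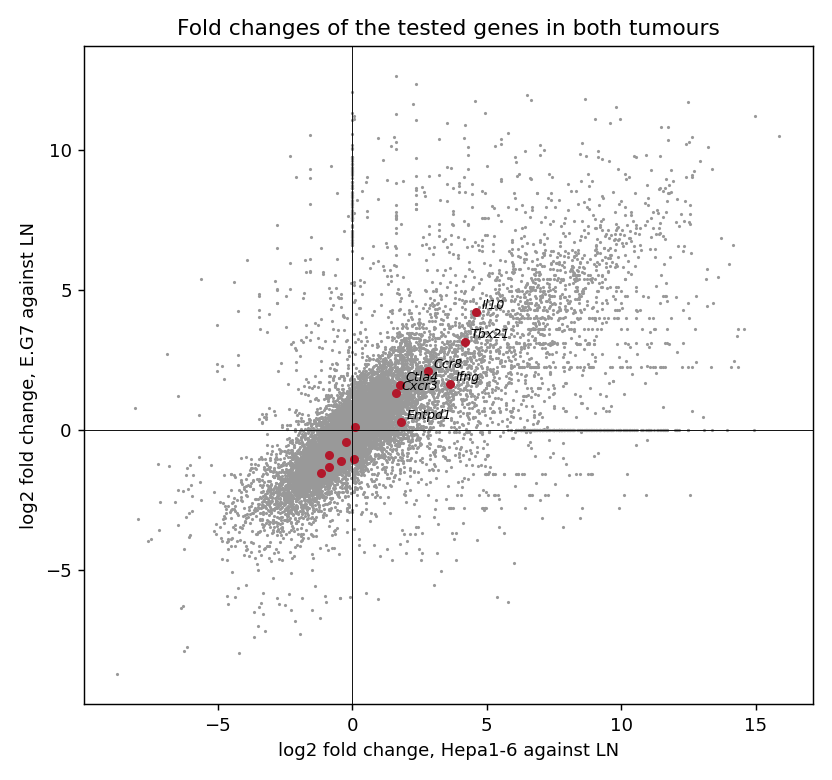
Log2 fold change against LN of the 20068 tested genes in Hepa1-6 (horizontal axis) and E.G7 (vertical axis) libraries, with those of the 15 fixed genes that are reported here as large points and those above 1 on the horizontal axis named. The correlation across genes is 0.66; dense lines on the axes are genes with no counts in LN and one tumour.

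Between the tumours, Th1 genes stood higher in Hepa1-6 than in E.G7 libraries. So did 13 of 14 Treg core genes, with camera adjusted p = 0.0015 but adjusted p = 0.053 with an estimated correlation. Macrophage and neutrophil markers (median log2 3.14) and CD8 T and NK markers (1.65) were also higher, each with adjusted p = 0.053 with an estimated correlation. Of 5 thymocyte genes 2 were higher and 2 lower in Hepa1-6, the lower ones being Dntt (2.84 against 46.6 CPM) and Arpp21 (0.144 against 22.9). The tumour antigen gene Trap1a stood at 0.0516 against 127 CPM. How far RNA of other cells moved the Th1, Treg core and Entpd1 differences was not tested. Tbx21 was 2.10-fold, Ifng 4.05-fold, Cxcr3 1.26-fold and Ccl5 3.16-fold higher in Hepa1-6. All 14 Th1 genes were higher (median log2 0.77, camera adjusted p = 5.35e-05, or adjusted p = 0.0289 with an estimated correlation). Entpd1 was 2.92-fold higher, at 182 ± 5.22 (SD, n = 4) against 62.5 ± 6.57 CPM (SD, n = 2, log2 1.54, SE 0.082, edgeR adjusted p = 4.04e-10), Il2ra 2.14-fold, Foxp3 1.63-fold, Ccr8 1.66-fold, Nt5e 1.39-fold, Il10 1.32-fold and Nrp1 1.29-fold. Ctla4 (1.12-fold, adjusted p = 0.0122) and Ikzf2 (1.15-fold, adjusted p = 0.0249) were called higher, but not with upper-quartile scaling (0.122 and 0.126), without a filter (0.246 and 0.139), with only the groups compared (0.154 and 0.099) or without E.G7 replicate 1 (0.149 and 0.147), and Ikzf2 also not without E.G7 replicate 2 (0.0922) or Hepa1-6 replicate 1 (0.0626) or 2 (0.0527). Gata3 (log2 -0.02, adjusted p = 0.761) and Bcl6 (log2 0.01, adjusted p = 0.979) were not called.

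Of the lists that passed with the preset correlation between the tumours, 5 of 21 also passed with an estimated one. These were the Th1 list, the interferon response (18 of 22 genes higher in Hepa1-6, 19 adjusted over the list alone, median log2 0.85, camera adjusted p = 9.96e-08, or adjusted p = 0.0289 with an estimated correlation; Iigp1 3.13-fold, Gbp2 4.22-fold), the cell cycle (21 of 22 lower, 22 adjusted over the list alone, median -1.02, adjusted p = 8.75e-11, or adjusted p = 0.0289 with an estimated correlation; Rrm2 3.44-fold and Stmn1 2.42-fold lower, beside Dntt at 2.84 against 46.6, Arpp21 at 0.144 against 22.9 and Trap1a at 0.0516 against 127 CPM), dendritic cell and MHC class II markers (8 of 10 higher, median 2.43, camera adjusted p = 0.00053, or adjusted p = 0.0289 with an estimated correlation; Cd74 5.58-fold, H2-Aa 5.50-fold) and hepatoma markers (8 of 9 higher, median 8.69, or 6.41 with bounds, camera adjusted p = 7.83e-07, or adjusted p = 0.0289 with an estimated correlation; Krt8 3440-fold). Without the genes under 1 CPM in LN the hepatoma list did not pass (adjusted p = 0.0653). Macrophage and neutrophil markers (14 of 14 higher, median 3.14; C1qa 11.6-fold, Mrc1 19.0-fold) and CD8 T and NK markers (7 of 10 higher, median 1.65; Cd8a 5.71-fold, Klrd1 3.25-fold) had adjusted p = 1.65e-06 and 0.00991, but adjusted p = 0.053 for each with an estimated correlation.

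A further group of lists was called higher in Hepa1-6 than in E.G7 libraries by camera with the preset correlation, but not with an estimated one. All 5 erythroid genes were higher (median log2 1.92, camera adjusted p = 0.00991; Hba-a1 4.6-fold, Hbb-bs 3.79-fold), as were 13 of 14 Treg core genes (median 0.44, adjusted p = 0.0015; Capg 1.74-fold), 8 of 10 Th2 genes (median 1.19, adjusted p = 0.0111; Il1rl1 3.38-fold, Il4ra 1.46-fold), 9 of 11 tissue chemokine receptors (median 1.01, adjusted p = 0.00488; Ccr1 7.54-fold, Ccr2 2.77-fold) and 7 of 10 hypoxia genes (median 1.34, adjusted p = 0.00302; Bnip3 4.57-fold, Ndrg1 2.82-fold). The same held for 11 of 14 handling-stress genes (median 0.78, adjusted p = 0.000666; Fos 2.18-fold, Atf3 6.84-fold) and 8 of 12 stromal and endothelial genes (median 1.86, adjusted p = 0.00991; Fn1 27.7-fold, Sparc 33.8-fold). Each of these 7 lists had adjusted p = 0.053 with an estimated correlation. The stromal call also ended without the genes under 1 CPM in LN (adjusted p = 0.151). The Th2 call also ended with the filter of 10 CPM (adjusted p = 0.104). Of 18 effector Treg genes 13 were higher and 1 lower (median 0.57, adjusted p = 0.0015, but adjusted p = 0.0535 with an estimated correlation). Of 10 suppressive mediators 8 were higher and 2 lower (median 0.71, adjusted p = 0.00991, but adjusted p = 0.0719 with an estimated correlation; Prf1 3.98-fold, Fgl2 3.20-fold).

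Glycolytic genes (10 of 14 higher, 11 adjusted over the list alone, median log2 0.42, camera adjusted p = 0.0015; Slc2a1 3.79-fold, Slc16a3 3.51-fold), NF-kB targets (9 of 12 higher, median 0.33, adjusted p = 0.0114; Bcl2l1 2.15-fold, Icam1 1.79-fold) and T cell receptor response genes (8 of 11 higher, median 0.24, adjusted p = 0.0399; Tnfrsf9 1.87-fold, Egr2 2.08-fold) also stood higher in Hepa1-6 libraries. With an estimated correlation their adjusted p was 0.0947, 0.0981 and 0.147, and the receptor response call also ended without E.G7 replicate 2 (0.055), with upper-quartile scaling (0.0731), with only the groups compared (0.11) and on the FPKM scales. Of 13 homing and rest genes 3 were higher and 8 lower (4 and 9 adjusted over the list alone; median -0.58, adjusted p = 0.0162, but adjusted p = 0.0548 with an estimated correlation), with Tcf7 12-fold lower and Id3 4.25-fold higher. Of 16 cholesterol synthesis genes 1 was higher and 6 lower (median -0.29, adjusted p = 0.00991, but adjusted p = 0.0606 with an estimated correlation), with Cyp51 2.27-fold and Insig1 1.63-fold lower. The lists that did not pass were Th17 (adjusted p = 0.454; Stat3 1.55-fold higher, Ccr6 2.50-fold lower), follicular helper (0.0839, or 0.0286 with the filter of 10 CPM, 0.0321 on log2(FPKM + 1), 0.0314 on log2(FPKM + 0.1) and 0.037 without genes under 1 CPM in LN; Btla 1.94-fold and Slamf6 1.53-fold lower), thymic Treg (0.524) and checkpoint receptors (0.346; Lag3 3.22-fold and Vsir 1.98-fold higher). B cell markers did not pass either (0.0562, or 0.0492 without LN replicate 4, 0.0283 without Hepa1-6 replicate 2, 0.0363 without a filter, 0.0226 with DESeq2, 0.0281 with limma-voom and 0.0499 with pan T cell scaling; Ighm 1.57-fold and Cd79a 1.97-fold lower). Thymocyte genes (0.781) had a median of 1.29 but a mean of -1.24 and a camera direction down, with Dntt 16.4-fold and Arpp21 153-fold lower.

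Tnfrsf11b, Gpx2, Cldn3, Rbp4 (a hepatoma list gene) and Igfbp3 had no count in E.G7 and were at least 2760-fold, 2690-fold, 1390-fold, 955-fold and 851-fold higher in Hepa1-6 libraries. Erbb4, Slc5a9, Dclk3 and Slc22a3 had no count in Hepa1-6 and were at least 705-fold, 702-fold, 690-fold and 406-fold lower, and Trap1a stood at 0.0516 ± 0.103 CPM (SD, n = 4), against 127 ± 7.92 CPM (SD, n = 2). Its Hepa1-6 counts were all in replicate 4, without which the fitted log2 difference went from -11.13 to -14.65. In all, 5228 genes were higher and 3925 lower in Hepa1-6 than in E.G7 libraries, 45.6% of those tested, with 2915 and 1280 changed by at least 2-fold. The tumours differed in cell line, day of harvest and number of libraries. They also differed in the log2 ratio of Xist to the sum of 4 Y-linked genes, which was 0.05 to 0.33 in Hepa1-6, -4.99 and -5.12 in E.G7 and -0.30 to -0.08 in LN libraries. No fit can part these differences from each other, and that of Xist also goes with the comparison of E.G7 with LN.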

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

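The tests of RNA from CD8 T or NK cells, of RNA from macrophages and of carry-over were chosen after the results were seen; the count of other splits was planned.

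Named genes whose change against LN differed between the tumours are given as the log2 change in Hepa1-6 minus that in E.G7, with the edgeR test between the tumours past its threshold for each. Among Treg and T helper genes the differences were Foxp3 0.71, Il2ra 1.09, Ctla4 0.16, Ikzf2 0.20, Nrp1 0.37, Tbx21 1.07, Cxcr3 0.33, Ifng 2.02, Entpd1 1.54, Nt5e 0.47, Ccr8 0.73 and Il10 0.41. Other genes of the T cell lists gave Ccl5 1.66, Cxcr6 1.01, Il1rl1 1.76, Ccr3 1.93, Rora -0.36, Ccr6 -1.32, Slamf6 -0.61, Cxcr5 -1.08, Gpr83 -0.40, Gzmb 0.95, Fgl2 1.68, Lag3 1.69, Tigit 0.39, Il4ra 0.55 and Stat6 0.62. Genes of homing, signalling and interferon responses gave Bcl2 -0.47, S1pr1 -0.66, Id3 2.09, Ccr2 1.47, Ccr1 2.91, Irf1 0.46, Rsad2 2.07, Usp18 1.60, Irf9 0.33, Tnfaip3 0.35, Nfkbia 0.31, Nr4a1 0.23 and Nr4a2 0.55. Genes of the cell cycle, metabolism and handling stress gave Ccnb1 -0.82, Rrm2 -1.78, Stmn1 -1.27, Tpi1 0.75, Slc2a1 1.92, Pgam1 0.30, Bnip3 2.19, Insig1 -0.70, Cyp51 -1.18, Atf3 2.77 and Junb 0.44.

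Markers of other cells differed between the tumours by the same test. The differences were Ighm -0.66, Cd79a -0.98, C1qa 3.53, Mrc1 4.25, Lyz2 1.84, Cd74 2.48, H2-Aa 2.46, H2-Eb1 2.40, Klrd1 1.70, Klrc1 1.59, Cd8a 2.51, Cd8b1 1.29 and Dntt -4.03 for blood and lymphoid cell markers. They were Alb 12.58, Krt8 11.75, Trf 3.44, Gpc3 3.34, Fn1 4.79, Sparc 5.08, Pdgfrb -2.85, Hba-a1 2.20 and Hbb-bs 1.92 for hepatoma, stromal and erythroid genes. Genes named for the size of their change gave Mmp12 5.37, Chil3 3.74, Tnfrsf11b 14.92, Krt19 10.97, Tspan12 10.74, Gucy1a1 -1.57, Slc16a5 -1.62, Rec8 -1.65, Sorcs2 -1.85 and Slc28a2b -1.62 in the Hepa1-6 comparison, and Pcdh10 -9.98, Dclk3 -12.07, Apod -5.15, Sema6a 0.79, Wif1 -9.39, Xist 4.81, Gpr15 0.46 and Gbp2b 3.98 in the E.G7 comparison. Values of genes with 0 to 3 counts in a tumour are fitted and are no bounds. Tnfrsf11b had no count in E.G7 and was at least 2760-fold higher in Hepa1-6, and Dclk3 had none in Hepa1-6 and was at least 690-fold higher in E.G7. With 3 counts each in E.G7, Alb, Krt19 and Tspan12 stood in Hepa1-6 at 6680 times (95% counting interval 2280 to 32400), 2180 times (745 to 10600) and 1860 times (636 to 9020) that level. Pcdh10, with 2 counts in Hepa1-6, stood in E.G7 at 1250 times (345 to 10300).

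Single libraries moved some of the 91 gene differences. Gucy1a1 went from -1.57 to -2.46 without Hepa1-6 replicate 2, and its call ended without E.G7 replicate 1 (adjusted p = 0.0847) or 2 (0.0773). Wif1, with Hepa1-6 counts in replicate 4 only, went from -9.39 to -13.97 without it. Krt19 went to 14.57 and 10.01, and Tspan12 to 9.80 and 14.34, without E.G7 replicates 1 and 2. Calls also ended for Gpr15 without E.G7 replicate 1 (0.0507) or 2 (0.107), for Nr4a1 without E.G7 replicate 2 (0.0509), for Ctla4 without E.G7 replicate 1 (0.149), and for Ikzf2 without E.G7 replicate 1 (0.147) or 2 (0.0922) or Hepa1-6 replicate 1 (0.0626) or 2 (0.0527).

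Of the gene lists, Th1 0.77, Th2 1.19, Treg core 0.44, effector Treg 0.57, suppressive mediators 0.71, homing and rest -0.58, tissue chemokine receptors 1.01, interferon response 0.85, NF-kB targets 0.33 and T cell receptor response 0.24 were the median differences of lists that passed camera between the tumours with the preset correlation. Of the 21 such lists, 5 also passed with an estimated one (Th1, interferon response, cell cycle, dendritic cell and MHC class II, and hepatoma, each with adjusted p = 0.0289 with an estimated correlation), and the others had adjusted p = 0.053 to 0.147 with an estimated correlation. Further medians were cell cycle -1.02, glycolysis 0.42, hypoxia 1.34, cholesterol synthesis -0.29, handling stress 0.78, macrophage and neutrophil 3.14, dendritic cell and MHC class II 2.43, CD8 T and NK 1.65, hepatoma 8.69 (6.41 with bounds), stroma and endothelium 1.86 and erythroid 1.92.

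A library stood far from the others of its group for 14 of 206 values considered, where chance gives about 1 in 20 of those tested. The 206 include values equal in all libraries of a group and genes not reported here, which were not flagged, so fewer were tested. The number after each gene is the gap to the nearest library as a share of the group's range, against a limit of 0.829. In LN libraries these were Ifng 0.874, with replicate 3 at 4.86 CPM, Gata3 0.943, Slamf6 0.908, Tigit 0.914, Mrc1 0.991, Usp18 0.875, Apod 1 and Pdgfrb 1. In Hepa1-6 libraries they were Gucy1a1 0.89, Sorcs2 0.92, Nfkbia 0.936, Alb 0.874, Wif1 1 and Xist 0.838. Apod and Pdgfrb had a count in a single LN library.

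Fits of only the 8 LN and Hepa1-6 libraries call fewer genes than the model of all groups. Of their 35 splits into groups of 4, only 1, the real one, called as many genes: 12631. The highest of the other splits called 0. Each other split mixes LN with Hepa1-6 libraries. The difference between the groups then adds to its spread and leaves few calls possible. The splits therefore cannot decide how often chance would give such a number.

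Th1 genes stood higher in both tumours, beside markers of myeloid cells and of CD8 T or NK cells. Yet the cells were sorted from CD4 T cells by the Foxp3 reporter. Of the CD8 T and NK list, Klrb1c was not higher in either tumour (0.981 CPM in LN, 0.597 in Hepa1-6 and 0.924 in E.G7). Ncr1 stood at 0, 0.483 and 0.111 CPM in that order. If the RNA of another cell type were the whole source, the excess of Th1 genes over LN would have the Hepa1-6 to E.G7 ratio of that cell's markers. Against macrophages the median log2 ratios were 1.24 for 10 Th1 genes and 3.19 for 14 macrophage genes, a difference of -1.96 (exact permutation test, two-sided p = 0.000214), which argues against macrophages as the whole source. Against CD8 T and NK cells the difference was -0.78 (1.24 against 2.02 for 8 genes, exact permutation test, two-sided p = 0.0549). That source therefore stays open. A one-sided form of the permutation test gave p = 0.0286, but in a direction taken after the results were seen. No conclusion is drawn from it. A Th1-like state of Treg cells in tumours, as in the title of the series, may account for the genes as well, and remains an untested hypothesis.

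Macrophage genes were also present in E.G7 libraries, and RNA carried over from Hepa1-6 libraries could put them there. Over all tested members, hepatoma genes stood in E.G7 libraries at a median of 0.241% of their Hepa1-6 level (9 genes) and macrophage and neutrophil genes at 11.5% (14 genes), or at 0.028% (5 genes) and 9.14% (12 genes) among those of at least 10 CPM in Hepa1-6, with hepatoma genes under 1 CPM in LN. Carried-over RNA would bring each hepatoma gene to at least the share of the macrophage genes, and 6 of the 9 lay under the lowest of these (5.25%), with Alb at 0.015% and Krt8 at 0.028%. That argues against carry-over as the whole source, although Trf (9.2%), Gpc3 (9.87%) and Apoa2 (238%) lay above it. Macrophages within the E.G7 tumours remain open as an untested source.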

How the results depend on the processing

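The alternatives of scaling to pan T cell genes and of leaving out genes under 1 CPM in LN were chosen after the data were seen. Over all alternatives, named genes kept direction and side of the threshold in 5162 cases, lost the call in 41, gained it in 10 and changed sign in 19; for lists the numbers were 1743, 77, 31 and 15. The Th1 list kept its direction and call in every alternative run for it, with medians of 1.78 to 1.85, 1.13 to 1.22 and 0.73 to 0.82 without single libraries. Lists were not tested against a fold of 1.5. With 2 E.G7 libraries, leaving out 1 assumes that the other varies like the other groups. Where no cause is named below, the cause was not tested.

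With a filter of 10 CPM, which tests fewer genes, 4294 genes were higher and 4129 lower in Hepa1-6 than in LN, 4050 were higher in E.G7 and 3084 higher in both, and the correlation of fold changes was 0.728. The correlation was 0.591 without a filter, 0.604 with DESeq2, 0.85 with only the groups compared, 0.627 without genes under 1 CPM in LN, and 0.612 to 0.669 without single libraries. Against a fold of 1.5, a stricter test by construction, 3095 genes were lower in Hepa1-6 than in LN, 4144 higher and 2876 lower in E.G7 than in LN, 2837 higher and 1369 lower in Hepa1-6 than in E.G7, and 2849 higher and 1988 lower in both tumours; 21 calls of named genes were lost, among them those of Foxp3 in Hepa1-6 against LN and between the tumours. On log2(FPKM + 1), with fewer genes, 3887 were lower in Hepa1-6, 3542 in E.G7 and 2756 in both; on log2(FPKM + 0.1) these were 3864, 3523 and 2701. With an estimated correlation camera called 12, 11 and 5 lists. Fry, which does not set a list against the other genes, called 25, 27 and 27 of 27 lists. With so many genes called, it hardly separates the lists. Scaling to pan T cell genes moved the median log2 change of all genes to 0.33 in Hepa1-6 and 0.29 in E.G7 against LN (upper-quartile scaling to -0.13 and -0.07), with 4040 genes lower in Hepa1-6 and 2630 lower in both.

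Sign changes concerned values near 0 or lists without a call, except Ikzf2. Bcl6 between the tumours was -0.01 with RLE scaling, DESeq2, log2(FPKM + 1) and the same without a filter, -0.05 with upper-quartile scaling and without a filter, -0.06 with limma-voom and with only the groups compared, -0.04 on log2(FPKM + 0.1), and -0.13 to 0.22 without single libraries. With upper-quartile scaling the Treg core list was at -0.15, Il2ra at -0.13 and Gata3 at -0.09 in Hepa1-6 against LN. With the filter of 10 CPM, Hepa1-6 against LN gave -0.09 for Th2, -0.03 for Treg core, -0.82 for B cell genes and -0.01 for Il2ra, and E.G7 against LN gave -0.39 for B cell genes. The same filter between the tumours gave 0.17 for Th17, -1.34 for thymocyte genes and 0.01 for Gata3. Thymocyte genes were at -1.20 on log2(FPKM + 0.1), and Th17 at 0.11 with limma-voom and 0.63 without genes under 1 CPM in LN. Without single libraries, B cell genes ranged from -0.02 to 0.69 in Hepa1-6 against LN, and between the tumours Th17 from -0.49 to 0.11 and Gata3 from -0.08 to 0.02. With scaling to pan T cell genes the thymic Treg list and Ikzf2 were each at 0.05 in Hepa1-6 against LN.

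Replicate numbers gave no clear pairing of the libraries. Correlations of the deviations of LN and Hepa1-6 libraries with the same number ran from -0.21 to 0.24. Of 4 Hepa1-6 libraries, 2 correlated best with their own number. With so few libraries these values cannot decide whether the numbers mark pairs. With the replicate block, 7325 genes were higher and 6065 lower in Hepa1-6 than in LN, 6170 and 4929 in E.G7 against LN, and 4900 and 3469 between the tumours. The block put Bcl6 at -0.20 and the Th17 list at 0.03 between the tumours, and ended only the call of the cholesterol list in Hepa1-6 against LN (0.53, adjusted p = 0.0536). Depth was close among libraries, and simulated 1.5-fold changes were often missed.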

Other observations

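The test of Xist and Y-linked genes below, and the gene families, were chosen after the data were seen. Of 13 families examined, killer lectin receptor genes, which NK and CD8 T cells use, were higher than in LN for 18 of 20 members in Hepa1-6 (median log2 7.22) and 16 of 20 in E.G7 libraries (5.74). Chemokine ligand genes were higher for 29 of 32 members in Hepa1-6 (6.92) and 23 of 32 in E.G7 (3.14). Granzyme genes were higher for 7 of 8 members in each tumour, with medians of 5.60 and 4.99. Fc receptor genes were higher for 7 of 8 members in Hepa1-6 and 8 of 8 in E.G7, with medians of 9 and 5.83. MHC class II genes were higher for 8 of 8 members in Hepa1-6 (7.67) and 6 of 8 in E.G7 (4.20). RLE, upper-quartile and pan T cell scaling left the sign of these medians unchanged. Killer lectin and MHC genes have near-identical copies, and medians include fitted values of genes absent from LN.

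The other families moved less evenly. Collagen genes were higher for 18 and lower for 7 of 30 members in Hepa1-6 (median log2 3.95), and for 13 and 4 in E.G7 (1.55). Keratin genes were higher for 11 and lower for 1 of 14 in Hepa1-6 (10.65), and for 5 and 1 in E.G7 (median 0). TNF receptor genes were higher for 13 and lower for 5 of 19 in Hepa1-6 (1.37), and for 11 and 7 in E.G7 (0.63), and chemokine receptor genes for 11 and 5 of 17 (1.64), and 11 and 3 (1.31). Integrin genes were higher for 18 and lower for 7 of 29 in Hepa1-6 (1.07), and for 10 and 8 in E.G7 (0.08, or -0.04 with upper-quartile scaling). Interleukin receptor genes were higher for 20 and lower for 7 of 36 in Hepa1-6 (0.75), and for 12 and 15 in E.G7 (-0.06, or 0.16 with pan T cell scaling, with 16 and 9). Of 83 ribosomal protein genes 4 were higher and 48 lower in Hepa1-6 (-0.33), but 18 and 16 with pan T cell scaling (-0.03), while 30 were higher and 2 lower in E.G7 (0.20), or 59 and 0 with pan T cell scaling (0.49) and 23 and 9 with upper-quartile scaling (0.09). Of 13 genes encoded in mitochondria 2 were higher and 8 lower in Hepa1-6 (-0.23, or 0.06 with pan T cell scaling, with 2 and 5). In E.G7, 0 were higher and 0 lower (0.05). With pan T cell scaling 7 were higher and 0 lower in E.G7 (0.33), and with upper-quartile scaling 0 and 1 (-0.07).

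Xist, the RNA of the inactive X chromosome, and 4 Y-linked genes were both present in LN and Hepa1-6 libraries. In LN, Xist averaged 158 CPM and the Y-linked sum 184 CPM, and 4 of 4 libraries held both above 10 CPM. That argues against each LN library coming from 1 mouse, and a pool of male and female mice is a candidate explanation that was not tested. In Hepa1-6 libraries Xist ran from 203 to 242 CPM and the Y-linked sum from 183 to 197 CPM. E.G7 replicates 1 and 2 had Xist at 8.29 and 7.03 CPM with a Y-linked sum of 264 and 244 CPM. The SD of the log2 ratio of Xist to the Y-linked sum was 0.10 over the LN and 0.13 over the Hepa1-6 libraries (n = 4 each).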
